A study of Rattus norvegicus with 8 samples.

How the data were processed

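Total RNA from the hippocampus of 8 male Wistar rats, 4 on standard feed (control) and 4 on the same feed with 0.1% coral calcium hydride (CCH), was labelled with Cy3 and hybridised to Agilent rat arrays, 1 array per rat, per the labels. Per the file headers and the labels, the authors extracted spot intensity with Agilent Feature Extraction 9.5, and the deposited processed signal is a linear, background-subtracted and detrended intensity with no normalization between arrays. The deposited value table equals this signal rounded to 3 significant digits (largest relative difference 0.00498), so it is no independent source. Its column medians were 80.2, 63.3, 69.2 and 66 for control replicates 1 to 4 and 102, 85.4, 76.9 and 71.8 for CCH replicates 1 to 4.

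Groups came from the sample titles and treatment labels. The free-text sample descriptions contradict them, since they place the arrays in a rat model of Parkinson's disease with lesioned and unlesioned sides and with saline or L-DOPA injections that cut across the diet groups, and they were not used. The design text also names plain coral calcium, but no sample has that feed. The 4 control arrays sat on slide 1 and the 4 CCH arrays on slide 2, each slide with its own scan, and the replicate number equals the position on the slide. Planned slide and scan blocks were therefore not run, because a slide term equals the diet term.

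Of 45018 spots per array 43379 were not controls and covered 41012 probes. Gene names came from a reference table of the GRCr8 assembly matched on RefSeq accessions, which named 15184 probes (37.0%) and 12206 genes. The array grid names the older assembly rn4, so no coordinates are given. Between 76.3% and 79.9% of spots were well above background, 0 were saturated, and 55 to 122 per array carried an outlier mark and were set to missing. The median coefficient of variation of replicate spots was 5.41% ± 0.323 (SD, n = 4) on the control slide and 4.06% ± 0.0911 (SD, n = 4) on the CCH slide. The median background was 33.3 and 34.9 (two-sided exact permutation p = 0.0286 for each, the smallest possible).

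The log2 processed signal minus each array's 75th percentile over non-control spots was averaged over spots of the same probe. A probe was tested if it was well above background on at least 4 of the 8 arrays, whatever their group, and had at least 3 values per group, which left 31617 probes, 12469 of them named. CCH was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The median log2 difference of all tested probes was 0.03. No correction for slide was possible. Array measures and list scores were compared by exact permutation over all 35 splits of the 8 arrays into 4 and 4, two-sided.

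Lists of genes were tested by limma's camera with a preset inter-gene correlation of 0.01, with 1 probe per gene (the brightest over all arrays), at least 5 tested members and adjustment over the 35 tested lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run beside it. The lists, fixed before the data were examined, were antioxidant enzymes, glutathione synthesis and conjugation, NRF2 pathway, oxidant-producing enzymes, respiratory complex I, respiratory complexes II to V, glycolysis and pyruvate metabolism, cytosolic heat shock response, endoplasmic reticulum stress, immediate early genes, glucocorticoid-responsive genes, circadian clock, cytokines and NF-kB inflammation, interferon and antigen presentation, glutamate signalling, GABA signalling, calcium channels, pumps and buffers, apoptosis, proteasome, ribosomal proteins, adult neurogenesis and proliferation, and neurotrophins and neuropeptides. Marker lists covered dentate granule neurons, CA pyramidal neurons, interneurons, astrocytes, microglia, oligodendrocytes, their precursors, endothelium and pericytes, meninges and fibroblasts, choroid plexus and ependyma, thalamus and habenula, neocortex and subiculum, striatum, and blood cells.

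Named genes followed a rule fixed before the data were examined. It took per direction the 12 called, non-overlapping probes with the largest difference and a proper gene symbol, 1 per gene, filled from the smallest unadjusted p where fewer were called. It added a fixed set of 16 antioxidant, NRF2, neurotrophin and activity genes, the 4 leading members of each called list, and up to 2 leading members of other lists. A few genes that the rule names are not reported here, although counts and list tests include them. Other clock genes and sibling probes were named after their values were seen.

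The comparisons were repeated, as set before the data were examined, with normexp background correction with an offset of 50, quantile normalization, median scaling, scaling to probes detected on all arrays, no detection filter, detection on all 8 arrays, keeping marked spots, a replicate block, eBayes with trend and robust settings, array weights, the deposited value table and 1 probe per gene. They were also repeated with an adjusted threshold of 0.1, an unadjusted threshold of 0.05 with a 1.5-fold change, other list tests, and leaving out each array. Because the mean spot signal is not in the files, normexp used the median spot and background signals. Cyclic loess and a covariate for the choroid plexus score were added after seeing the data.

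The pipeline was tested on simulated data with 31617 probes and 4 arrays per group. It recovered 16%, 66%, 87.6% and 95.2% of seeded probes at log2 changes of 0.5, 1, 2 and 3, and 5.02% of calls were false. With 9719 genes, camera called 1 list over 20 runs of 35 lists with no change and found a list seeded at a log2 of 0.2 in 20 of 20 runs, with genes simulated as independent. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.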

Results

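Gene expression was measured in the hippocampus of 8 male Wistar rats with 1-colour Agilent rat arrays, 1 array per rat. The 4 control rats ate a standard laboratory feed and the 4 CCH rats ate the same feed with 0.1% coral calcium hydride, a hydrogen-bearing powder made from coral calcium. The rats were 6 weeks old at the start and 8 weeks old when killed. Each array held 43379 non-control spots for 41012 distinct probes. The 75th percentile of the processed signal was 611 ± 61.0 (SD, n = 4) on the control arrays and 732 ± 110 (SD, n = 4) on the CCH arrays (two-sided exact permutation p = 0.0857). Between 33091 and 34643 spots per array were well above background. The number of arrays limits the precision of each value. The 4 control arrays shared slide 1 and the 4 CCH arrays slide 2, each slide with its own scan, so slide, scan and diet cannot be told apart in any comparison below. The free-text descriptions of the samples speak of a lesion model and drug injections, which contradicts their titles and treatment labels, and the groups follow the titles and treatment labels.

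The study's title asks about antioxidant ability, and the genes for antioxidant enzymes fixed before the data were examined gave no call between CCH and control. Sod1, the cytosolic superoxide dismutase, stood at a log2 signal of 6.21 ± 0.03 (SD, n = 4) above the array's 75th percentile in the controls and 5.95 ± 0.21 (SD, n = 4) in CCH. The difference was -0.26 ± 0.12 (SE, adjusted p = 0.333), with -0.24 on its second probe, and -0.16 without CCH replicate 1. Catalase (Cat), which breaks down hydrogen peroxide, differed by 0.34 ± 0.17 (SE, adjusted p = 0.399), and Gpx1, a glutathione peroxidase, by -0.45 ± 0.25 (SE, adjusted p = 0.447; -0.50 on its second probe and -0.12 with a choroid plexus covariate chosen after seeing the data). The mitochondrial superoxide dismutase Sod2 differed by -0.05 ± 0.10 (SE), Prdx6 by -0.20 ± 0.15 (SE) and the lipid-peroxide reductase Gpx4 by 0.09 ± 0.19 (SE). Sod2 was at -0.01 without control replicate 3 and Prdx6 at -0.11 without control replicate 4. The difference in Gpx4 went to -0.08 with array weights and to -0.11 without CCH replicate 1. Txnrd1 differed by 0.17 ± 0.12 (SE) on its brightest probe (0.08 without CCH replicate 1). Its other probes were at -0.43 ± 0.13 (SE, limma adjusted p = 0.166) and 0.11. Over the list of antioxidant enzymes, 16 of 31 members were higher in CCH and 15 lower, with a mean log2 difference of -0.02 and a median of 0.00 (camera adjusted p = 0.970). None of these members was called by limma over all probes or adjusted over the list alone, and 1 higher and 1 lower reached an unadjusted p under 0.05 (Msra at 0.30 and Txn1 at -0.23).

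The redox regulators also stayed short of the threshold. Nfe2l2, which encodes the transcription factor NRF2, differed by a log2 of -0.24 ± 0.15 (SE, adjusted p = 0.499), and its inhibitor Keap1 by -0.13 ± 0.09 (SE, adjusted p = 0.551). The NRF2 targets Hmox1, Nqo1 and Gclc differed by -0.24 ± 0.23, -0.11 ± 0.18 and 0.05 ± 0.13 (SE). Nfe2l2 was at -0.13 without control replicate 1, and Hmox1 ran from -0.38 to -0.09 with 1 array left out. Nqo1 was at 0.01 without control replicate 1 and at 0.00 without CCH replicate 3. Gclc was at -0.04 both with normexp background correction and with array weights and at -0.06 without CCH replicate 1. Of 26 tested members of the NRF2 pathway 10 were higher and 16 lower (camera adjusted p = 0.296). They were led by the glutathione-conjugate exporter Abcc1 at -0.46 ± 0.10 (SE, adjusted p = 0.0853) and malic enzyme Me1 at -0.25. Abcc1 was the 1 member called lower when adjusted over the list alone. Glutathione synthesis and conjugation genes, led by Gsto2 at 0.46 (0.20 with normexp) and Ggt7 at 0.27, were higher for 14 and lower for 10 of 24 (camera adjusted p = 0.970). Oxidant-producing enzymes were higher for 4 and lower for 11 of 15 (camera adjusted p = 0.384), with the NADPH oxidase subunit Ncf1 at -0.29 and Nox1 at -1.53 ± 0.75 (SE). Nox1 was at -5.87, -3.13, -2.68 and -5.89 on control replicates 1 to 4, and its difference was -0.95 without control replicate 3 and -0.65 with normexp background correction. Respiratory chain genes of complexes II to V were lower for 26 of 29, with a mean log2 of -0.08 (camera adjusted p = 0.0689), a mean that was -0.01 without CCH replicate 1. The list passed without control replicate 1 (camera adjusted p = 0.0232), CCH replicate 3 (0.0158) or CCH replicate 4 (0.0104). It also passed with scaling to probes detected on all arrays (0.0412) and with the trend setting (0.0388), where the list test used no robust setting. The range over all alternatives was 0.0104 to 0.971. Their leading members were Atp5f1b at -0.19 and Cox6c at -0.27 (-0.11 without CCH replicate 1 and -0.14 with array weights). Complex I genes were lower for 17 of 26 (camera adjusted p = 0.630), with Ndufv3 at 0.39 ± 0.09 (SE, adjusted p = 0.0936) and Ndufs5 at -0.21 (-0.11 without CCH replicate 1). Glycolysis and pyruvate genes were higher for 11 and lower for 12 of 23 (camera adjusted p = 0.630), with Pdhb at 0.23 and Pdk4 at -0.88, well above background on 2 of 4 CCH arrays (-0.35 with normexp and -0.56 without CCH replicate 3). The neurotrophin Bdnf differed by -0.11 ± 0.12 (SE, 0.22 on its other probe and -0.04 without control replicate 4). The activity-induced Fos differed by 0.33 ± 0.09 (SE, adjusted p = 0.132). Gclm failed the detection filter and Mt2A had no named probe.

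**Figure D1:**
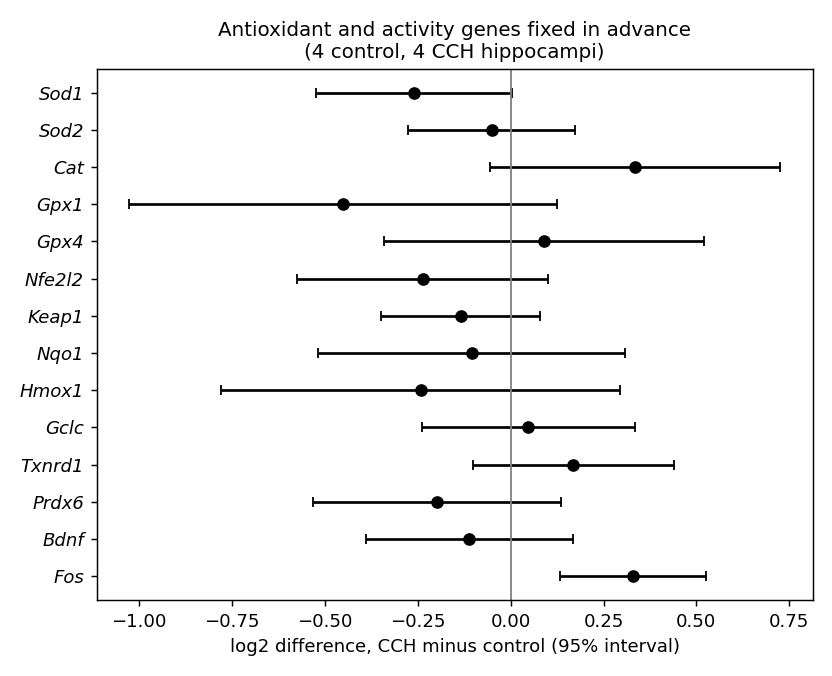
Log2 difference, CCH minus control, of the 14 tested antioxidant, NRF2-pathway and activity genes fixed before the data were examined; points are differences between the means of 4 CCH and 4 control arrays and bars are 95% intervals from limma without adjustment. On each gene's brightest probe, the interval of Fos lies above 0 and those of the other genes include 0. No gene was called after adjustment. Other probes of Sod1 (-0.24) and Txnrd1 (-0.43), not drawn, had an unadjusted limma p of 0.0281 and 0.00841. Gpx4, Nqo1 and Gclc change sign under some alternatives.

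Across the 31617 tested probes, 55 were called between CCH and control, 24 higher and 31 lower, with absolute log2 differences between 0.57 and 2.86. Rbm38, an RNA-binding protein gene, rose 7.27-fold (probe A_44_P126355; log2 2.86 ± 0.29, SE, n = 4 per group, adjusted p = 0.0271). Terc, the RNA component of telomerase, rose 2.21-fold (log2 1.14 ± 0.15, SE, adjusted p = 0.0399). Cd3e, a subunit of the T-cell receptor complex, rose 2.03-fold (log2 1.02 ± 0.14, SE, adjusted p = 0.0432). The pancreatic lipase gene Pnlip rose by a log2 of 0.93, the complex I subunit gene Ndufc2 by 0.86, Mk1 by 0.93, Ppp1r14bl by 0.82, the urate transporter gene Slc22a12 by 0.77 and Jkampl by 0.76 (adjusted p between 0.0271 and 0.0481). These probes were mostly dim, with Rbm38 at -5.32 ± 0.32 (SD) and Ppp1r14bl at -5.86 ± 0.14 (SD) in the controls. With normexp background correction Rbm38 was at 1.18, Terc at 0.60 and Cd3e at 0.50, all still called, while Mk1 at 0.30, Ndufc2 at 0.30, Slc22a12 at 0.22, Jkampl at 0.34 and Ppp1r14bl at -0.06 were no longer called. Ceacam4 at 0.94, the chaperonin subunit gene Cct6a at 0.89 and Cyp4a2 at 0.83 stayed just above the threshold (adjusted p of 0.0525, 0.0525 and 0.0529), and with normexp they were at 0.28, 0.22 and -0.02.

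The largest decrease among called named genes was that of Fcgr2b, the inhibitory Fc gamma receptor of microglia and other immune cells, which fell 2.35-fold (log2 -1.23 ± 0.16, SE, n = 4 per group, adjusted p = 0.0399). Ppargc1a, which encodes the mitochondrial biogenesis coactivator PGC-1alpha, fell 1.75-fold (log2 -0.81 ± 0.11, SE, adjusted p = 0.0486). Gria4, an AMPA-type glutamate receptor subunit, fell 1.70-fold (log2 -0.76 ± 0.10, SE, adjusted p = 0.0399), and the vesicle motor gene Myo5a fell 1.83-fold (log2 -0.87 ± 0.10, SE, adjusted p = 0.0276). Aff4, a scaffold of the super elongation complex, fell by a log2 of 0.87, Jade2, a subunit of histone acetyltransferase complexes, by 0.98 and the arginine- and serine-rich Rsrp1 by 1.07. The other named decreases were Pnma3 at -1.06, the phosphodiesterase gene Pde3a at -0.99 with only 1 of 4 CCH arrays well above background (-0.34 and no longer called with normexp), the RAS pathway scaffold Shoc2 at -0.75, the prefoldin-like Uri1 at -0.73 and the protocadherin gene Pcdh7 at -0.71. Of the 23 called named genes 8 had 11 other tested probes, and those differed less. The called probes were picked for their small p, which favours large differences. The other probe of Ndufc2 was at -0.03, of Slc22a12 at -0.18, of Mk1 at 0.49, of Rsrp1 at 0.04, of Pnma3 at -0.14 and of Gria4 at 0.11, while those of Aff4 were at -0.59, -0.42, -0.08 and 0.08. In all 55 called probes the groups did not overlap, as in 3568 (11.3%) of all tested probes against 2.86% by chance. By limma 4862 probes (15.4%) reached an unadjusted p under 0.05. Leaving out any 1 array other than CCH replicate 1 gave 0 or 1 called probe, leaving out CCH replicate 1 gave 708, and a covariate for choroid plexus markers, chosen after seeing the data, left 1, Rbm38.

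**Figure D2:**
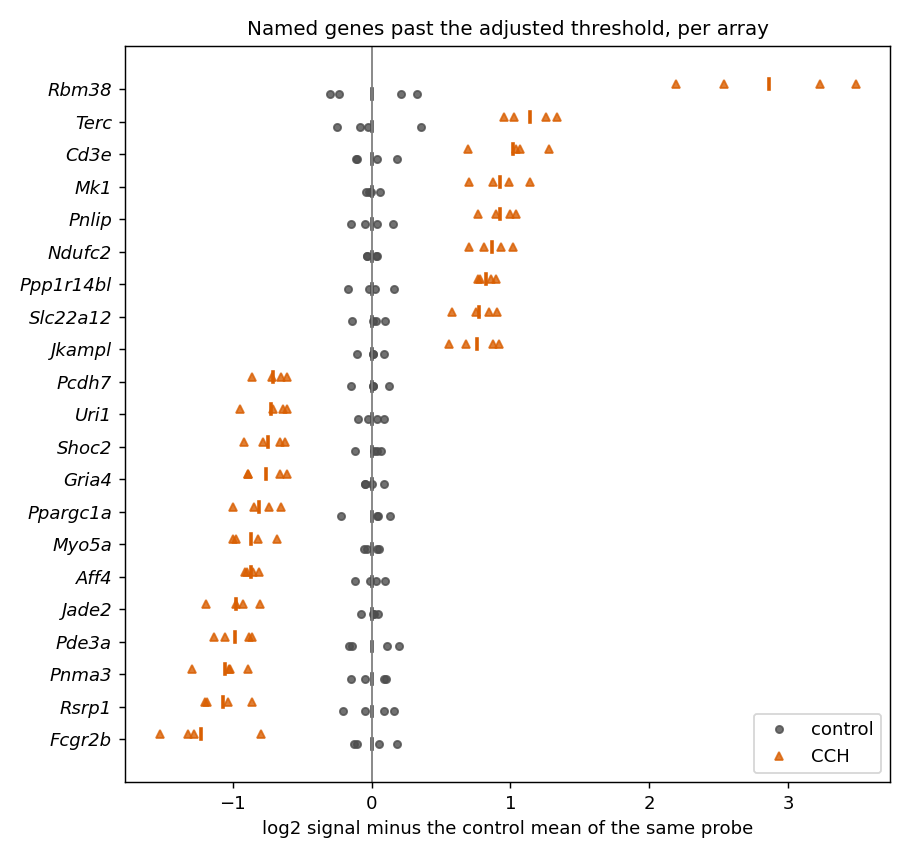
Log2 signal of the 9 named genes called higher and the 12 named genes with the largest called decreases in CCH, minus the control mean of the same probe; circles are the 4 control arrays, triangles the 4 CCH arrays and vertical ticks the group means. Within each gene the control and CCH arrays do not overlap; Ppp1r14bl changes sign with normexp background correction.

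Of 35 tested gene and marker lists, camera called 5. Oligodendrocyte markers were higher for 14 of 16, by a mean log2 of 0.25 (camera adjusted p = 1.73e-04; adjusted p = 0.782 with an estimated correlation), and 7 were called higher when adjusted over the list alone against 0 over all probes. Their leading members were the myelin genes Mal at 0.68 ± 0.10 and Ugt8 at 0.78 ± 0.12 (SE, both with an adjusted p of 0.0529), Ugt8 at 0.34 with normexp. They were followed by the myelin gene Mobp at 0.52 with -0.11 on its other probe, and the lineage factor Olig1 at 0.45. Oligodendrocyte precursor markers were higher for 6 of 7, by a mean of 0.24 (camera adjusted p = 0.0374; adjusted p = 0.730 with an estimated correlation). They were led by the growth factor Bmp4 at 0.78 ± 0.14 (SE, adjusted p = 0.0634), Neu4 at 0.34, Matn4 at 0.31 (0.12 with normexp) and Bcas1 at 0.23 (-0.10 on its other probe and 0.12 without CCH replicate 3), and 3 were called higher when adjusted over the list alone. Microglia markers were lower for 14 of 18, by a mean of -0.21 (camera adjusted p = 0.00751; adjusted p = 0.730 with an estimated correlation). Beside Fcgr2b, the only member called over all probes or adjusted over the list alone, the microglial signalling adaptor Tyrobp was at -0.44 ± 0.13 (SE, adjusted p = 0.180), Laptm5 at -0.33 and Aif1, also known as Iba1, at -0.40 (-0.26 without CCH replicate 1). All 4 CCH arrays lay above all 4 control arrays in both oligodendrocyte-lineage scores and below them in the microglia score (two-sided exact permutation p = 0.0286 each, the smallest 4 against 4 can give, and 0.257 after adjustment over 36 lists).

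Ribosomal protein genes were lower for 52 of 59, by a mean log2 of -0.10 (camera adjusted p = 2.15e-06; adjusted p = 0.880 with an estimated correlation). Their scores overlapped between the groups (two-sided exact permutation p = 0.114, and 0.514 after adjustment over 36 lists). The leading members were Rpl32 at -0.28, Rpl24 at -0.22 and Rpl3 at -0.22, and without CCH replicate 1 the mean was -0.05. Choroid plexus and ependyma markers were lower for all 15, by a mean of -1.73 (camera adjusted p = 0.00446; adjusted p = 0.971 with an estimated correlation). The choroid scores also overlapped (two-sided exact permutation p = 0.229, and 0.748 after adjustment). Ttr, the transthyretin gene of the choroid plexus, was at 6.90 ± 1.32 (SD, n = 4) in the controls and 3.86 ± 3.54 (SD, n = 4) in CCH. Sostdc1, Kcnj13 and Tmem72 differed by -3.11 ± 1.71, -2.39 ± 1.39 and -2.17 ± 0.99 (SE), Tmem72 with 3 of 4 CCH arrays well above background. Without CCH replicate 4 Ttr, Sostdc1 and Kcnj13 differed by -1.93, -1.96 and -1.33, and Tmem72 by -1.12 without CCH replicate 2 and by -0.63 with normexp. CCH replicates 2 and 4 held the low choroid scores of -2.80 and -2.91, CCH replicates 1 and 3 were at 1.03 and 1.23, and the controls ran from -0.62 to 1.73. Meninges and fibroblast markers were lower for 11 of 15 (camera adjusted p = 0.547), with Slc13a3 at -0.77 and Dcn at -0.36. Without control replicate 1, 2, 3 or 4 in turn, Slc13a3 was at -0.20, -1.30, -0.38 and -1.20 and Dcn at -0.09, -0.59, -0.19 and -0.54, and Dcn was at -0.17 without CCH replicate 4. Their scores ran from -1.66 to 1.95 in the controls and from -0.996 to 0.34 in CCH. That list passed without control replicate 2 (adjusted p = 0.0150, in a range of 0.0150 to 0.972). The choroid call ended without CCH replicate 2 (adjusted p = 0.0943) or CCH replicate 4 (0.0826), in a range over all alternatives of 1.63e-05 to 0.971. The precursor call ended without control replicate 2 (0.0779), control replicate 3 (0.0601), CCH replicate 2 (0.0964) or CCH replicate 3 (0.0513) and with the mean of a gene's probes (0.0626), in a range of 0.0182 to 0.730. With normexp the ribosomal, microglia and choroid calls ended (adjusted p of 0.0519, 0.0624 and 0.0624, in ranges of 3.47e-08 to 0.880, 0.00299 to 0.730 and 1.63e-05 to 0.971).

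**Figure D3:**
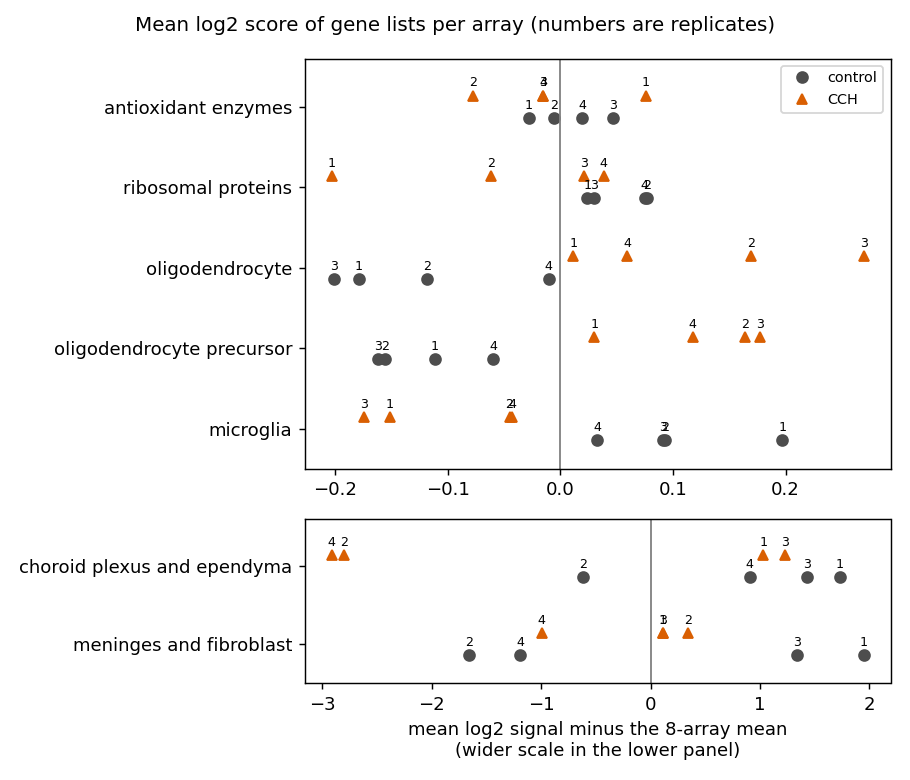
Mean log2 signal of 7 gene lists on each of the 4 control arrays (circles) and 4 CCH arrays (triangles), relative to the mean of all 8 arrays, with the replicate number above each point and a wider scale in the lower panel. The groups separate for oligodendrocytes, their precursors and microglia, while CCH replicates 2 and 4 lie apart in the choroid plexus score.

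Neuronal markers were not called as lists. CA pyramidal neuron markers were higher for 9 of 10, by a mean log2 of 0.19 (camera adjusted p = 0.225), with the CA1 gene Wfs1 at 0.57 ± 0.16 (SE, adjusted p = 0.159). All 4 CCH arrays lay above all 4 controls in that score (two-sided exact permutation p = 0.0286, and 0.257 after adjustment over 36 lists). Interneuron markers were lower for 8 of 11 (camera adjusted p = 0.225). Among them Reln, the extracellular matrix protein reelin, was at -0.79 ± 0.16 (SE, adjusted p = 0.0770; 0.49 on its other probe) and was called when adjusted over the list alone, and Sst was at 0.30. Only 4 dentate granule neuron markers were measured, too few for the test, with 3 higher and 1 lower (Trpc6 at -0.17, or -0.08 without CCH replicate 3, and Prox1 at 0.12, the latter at -0.03 with normexp). Astrocyte markers were higher for 7 and lower for 7 of 14 (camera adjusted p = 0.966), with the bicarbonate transporter gene Slc4a4 at -0.34 and S100b at 0.73 (0.46 with normexp). Endothelial and pericyte markers were higher for 9 and lower for 8 of 17 (camera adjusted p = 0.966), with Pdgfrb at 0.33 and Cdh5 at -0.58 (-0.34 without control replicate 1). Blood cell markers were higher for 6 and lower for 4 of 10 (camera adjusted p = 0.809), with Cd3e called both over all probes and adjusted over the list alone, and S100a8 at -0.85, well above background on 2 of 4 CCH arrays (-0.33 with normexp).

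None of the receptor, calcium and stress lists was called. Glutamate signalling genes were higher for 17 and lower for 13 of 30 (camera adjusted p = 0.966). Gria4 was called lower over all probes, 3 members were called lower when adjusted over the list alone, and the kainate receptor gene Grik1 was at -0.56 ± 0.11 (SE, adjusted p = 0.0710). GABA signalling genes were higher for 9 and lower for 12 of 21 (camera adjusted p = 0.369). They included the GABA-A receptor subunit gene Gabra3 at -0.65 ± 0.12 (SE, adjusted p = 0.0626), called lower when adjusted over the list alone, and the chloride transporter gene Slc12a2 at -0.37. Calcium channels, pumps and buffers were higher for 28 and lower for 18 of 46 (camera adjusted p = 0.630), and 1 was called higher and 4 lower when adjusted over the list alone. The calcium-sensing receptor gene Casr was at 0.96 ± 0.17 (SE, adjusted p = 0.0577; 0.33 with normexp) and the neuronal calcium sensor gene Hpcal4 at -0.64 ± 0.11 (SE, adjusted p = 0.0583). Endoplasmic reticulum stress genes were higher for 15 and lower for 6 of 21 (camera adjusted p = 0.369), although the sensor Atf6 was at -0.56 and Atf4 at -0.27. Proteasome genes were higher for 12 and lower for 17 of 29 (camera adjusted p = 0.567), with Psmd7 at -0.28 (0.16 and -0.26 on its others) and Psme1 at -0.31 (-0.20 without control replicate 1). Apoptosis genes were higher for 14 and lower for 13 of 27 (camera adjusted p = 0.933). They included the death effector Bax at 0.35 ± 0.07 (SE, adjusted p = 0.0798), called higher when adjusted over the list alone. Neurogenesis and proliferation genes were higher for 12 and lower for 7 of 19 (camera adjusted p = 0.630). They included the ribonucleotide reductase gene Rrm2 at -0.64 ± 0.12 (SE, adjusted p = 0.0710; -0.24 with normexp), called lower when adjusted over the list alone, and the progenitor filament gene Nes at -0.49. In 7 lists the median, the mean and the direction of camera's test differed in sign: calcium, apoptosis, antioxidant enzymes, glutathione, endothelial, thalamus and neocortex.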

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

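All tests of explanations in this part, and the limits that decide them, were chosen after the result was seen, apart from the counts of called probes in other splits of the arrays. Those counts of probes were fixed before the data were examined, although what they would show was not.

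Several genes had 1 array far from the other 3 of its group, by the gap to its nearest neighbour as a share of the group's range. Hspa1a, the stress-induced HSP70 gene, was at a log2 of -0.08 in CCH replicate 1 with the nearest CCH array at 0.77 (ratio 0.943). The microglial adaptor gene Tyrobp was high in control replicate 1 (2.06 against 1.65, ratio 0.916) and low in CCH replicate 1 (1.06 against 1.365, ratio 0.904). The CA1 gene Wfs1 was at 1.40 in control replicate 4 with the nearest at 2.00 (ratio 0.965). S100b (ratio 0.832), the malic enzyme gene Me1 (0.859) and the repressor gene Bcl6 (0.897) stood apart in CCH replicate 1. Ceacam4 stood apart in CCH replicate 3 (0.842), Ndufs5 in control replicate 2 (0.910), Nfil3 in control replicate 3 (0.860) and Rpl24 in control replicate 1 (0.849).

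Among the list scores, control replicate 2 stood apart for glycolysis (ratio 0.834), endoplasmic reticulum stress (0.918), proteasome (0.877) and astrocytes (0.860), and CCH replicate 1 for immediate early genes (0.834), where its score was -0.19 and the nearest 0.10. The median background of CCH replicate 1 was 34.5 against 35 on the other CCH arrays (ratio 1). In all, 18 of 310 groups of 4 had an array this far out, where chance gives about 1 in 20, or 15.5. CCH replicate 1 held 7 of them and control replicate 2 held 5.

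The 55 called probes, with Rbm38 and Fcgr2b at their head, were weighed against other explanations. Only the real split gave as many, 1 of 35, the smallest share possible, and the highest of the others gave 3, which argues against chance, although at an unadjusted p under 0.05 the real split gave 4862 and the highest other, control replicates 1, 3 and 4 with CCH replicate 1, gave 4684. Of the 55 probes 55 were still called after cyclic loess, which argues against an average intensity trend between the slides as the whole cause. Cyclic loess does not remove differences of single probes, and with normexp background correction 41 of the 55 were still called. Direction went with brightness among the listed named genes. Those called higher had control means of -5.86 (Ppp1r14bl) to -1.76 (Pnlip). Those called lower ran from -1.55 (Pnma3) to 4.33 (Myo5a), apart from Pde3a at -5.82. The median background was 33.3 on the control slide and 34.9 on the CCH slide, so a background difference stays open for the dim probes. A whole-transcript change of similar size on every probe was weighed by 3 rules, tried after the intervals were seen. By the strictest, the other probes of Gria4, Ndufc2, Pnma3, Rsrp1 and Slc22a12 had 95% intervals up to at most 0.474 of the called difference. That argues against such a change only if the called difference is exact and the probes are equally sensitive. The called probe was picked as the called probe of its gene with the smallest p. Such a choice favours a large difference and tilts the ratio toward low values. For Ndufc2 the ratio rests on a called 0.86, which was 0.30 with normexp. By that rule Mk1 and Usp7 cannot be told (up to 0.848 and 0.648). In Aff4 the probes at 0.08 and -0.08 reached at most 0.182 and 0.449, while others reached 0.732 and 1.04. That argues against a similar change on all probes of Aff4 under the same conditions. The other rules marked 6 genes each, adding Aff4 or Usp7, with the same called probes as reference. A change of single transcript forms, a difference in single probes between slides and an effect of the diet all stay open, since 0 slides hold both groups and a slide or scan effect cannot be told apart from diet.

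The choroid plexus markers, Ttr and Sostdc1 among them, were low on CCH replicates 2 and 4. Low scores were not seen in every CCH animal, as 2 of the 4 CCH arrays lay at or above the control mean of 0.86. With control scores from -0.62 to 1.73, a smaller shift in every animal cannot be told apart from that spread. The 15 markers deviated from their group means together, with a mean pairwise correlation across the arrays of 0.769 against an upper bound of 0.138 for 1000 random lists, and uneven amounts of choroid plexus in the dissected tissue are a candidate explanation. Ttr was at 6.47, 1.09, 7.34 and 0.56 on CCH replicates 1 to 4 and at 7.66, 4.95, 7.79 and 7.20 on control replicates 1 to 4. No biological explanation was tested.

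The number of called lists was also weighed against chance. Of the 35 splits of the 8 arrays 21 called at least 5 lists, and the highest of the other splits called 12. Chance therefore cannot be excluded for the number of called lists, and a camera call at the preset correlation does not by itself set the diet groups apart. Correlations estimated within the called lists were 0.248 for ribosomal proteins, 0.300 for oligodendrocytes and 0.769 for choroid plexus, against the preset of 0.01. Those for microglia and precursors were 0.0561 and -0.0274. In the simulation genes were independent, so its list result does not cover such correlation.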

How the results depend on the processing

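Cyclic loess and the choroid plexus covariate were chosen after seeing the data, and the other alternatives before. The planned slide and scan blocks were not run, since each slide and scan holds 1 group and diet cannot be told apart from them.

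Ribosomal protein, microglia and oligodendrocyte-lineage genes kept the direction of their mean in every alternative. Leaving out 1 array gave means of -0.13 to -0.05 for ribosomal proteins, -0.23 to -0.18 for microglia, 0.21 to 0.29 for oligodendrocytes, 0.23 to 0.28 for their precursors and -2.42 to -1.04 for choroid plexus. The number of called lists was 5, and 2 with normexp, 0 with an estimated correlation, 1 with fry and 3 to 7 with 1 array left out. Over 35 lists and 805 comparisons, 730 kept direction and side of the threshold, 19 lost the call, 11 gained one and 45 changed sign. Over 114 named probes and 2497 comparisons these counts were 2186, 211, 90 and 10, and 53 of the probes moved by over 1.5 times in at least 1 alternative, 28 of them with 1 array left out. Only called results can lose a call. The 211 therefore belong to the 21 called named probes, with at most 22 comparisons each, and the 19 to the 5 called lists, with 23 each. Alternatives that change only the test leave a mean as it was, so direction cannot change there.

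The 55 called probes (24 higher, 31 lower) depended on the settings. There were 246 (69 higher, 177 lower) with normexp, of which 41 were among the 55, and 29 (10 and 19) with no detection filter, 20 of them among the 55. Requiring signal well above background on all 8 arrays gave 209 (99 and 110) with 54 of the 55, out of 29561 tested, and the dim probes, the number tested and the variance prior were not separated. Signal over background limits values such as that of Ppp1r14bl, at -5.86 in the controls. Trend and robust settings gave 220 (95 and 125), array weights 1339 (743 and 596) and cyclic loess 260 (90 and 170), with 53, 55 and 55 of the original calls. The looser thresholds gave 704 (330 and 374) at an adjusted p under 0.1 and 1006 (436 and 570) at an unadjusted p under 0.05 with a 1.5-fold change, more by construction. Quantile normalization, median scaling, scaling to detected probes, kept spots and the value table gave 46 to 69, with 46 to 55 of the 55. With 1 probe per gene there were 50 of 9740 tested, with 18 of the 55. That setting drops probes with no gene name, 32 of the 55 among them.

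Leaving out 1 array gave 0 to 708 called probes, 0 to 409 higher and 0 to 299 lower. The count was 0 without control replicate 1 or 4 or without CCH replicate 2, 3 or 4, and 1 without control replicate 2 or 3 (0 of these among the 55); 3677 to 4657 probes then had an unadjusted p under 0.05. It was 708 without CCH replicate 1, including all 55. The choroid plexus covariate left 1 probe (1 higher, 0 lower), Rbm38, with 3997 at an unadjusted p under 0.05. With it all 55 kept their direction, with a median absolute log2 of 0.84 against 0.83 before, while their median SE went from 0.100 to 0.116 and their adjusted p ran from 0.00195 to 0.154. The wider error, the lost degree of freedom and the adjustment were not separated. Except where stated, the cause was not tested.

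A block by replicate number, in limma, gave 0 called probes (0 higher, 0 lower), against 4966 at an unadjusted p under 0.05 with it. Same-number residual correlations were 0.145, 0.0797, -0.00519 and 0.246, and the highest of all, 0.441, joined control replicate 2 to CCH replicate 4. They show no clear pairing by number. The number equals the position on the slide, and an effect of position was not tested. With the block the choroid plexus list had a camera adjusted p of 2.73e-05, against 0.00446 without it.

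Signs changed only for values that were not called, apart from Ppp1r14bl. With normexp, mean log2 differences were -0.0562 for Ppp1r14bl, -0.0172 for Cyp4a2, -0.0401 for Gclc, -0.0307 for Prox1, -0.00114 for glutamate signalling, -0.0316 for neurogenesis, -0.0197 for endothelium and -0.0463 for blood cells. With array weights they were -0.0797 for Gpx4, -0.0384 for Gclc, -0.00218 for neurogenesis, -0.0206 for endothelium and -0.0426 for blood cells. Detection on all 8 arrays gave 0.000525 for glycolysis and 0.000392 for glucocorticoid-responsive genes. Glutamate signalling was also at -0.0126 with quantile normalization, -0.00782 with median scaling, -0.0122 with scaling to detected probes, -0.000871 with the mean of a gene's probes and -0.0242 with cyclic loess, where endothelium was at -0.00407.

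With 1 array left out, Gpx4 ran from -0.106 to 0.203, Nqo1 from -0.246 to 0.00870 and Gclc from -0.0580 to 0.132. Among the redox and energy lists, antioxidant enzymes ran from -0.0444 to 0.00688, glutathione from -0.0844 to 0.0133, oxidant-producing enzymes from -0.231 to 0.0519, complex I from -0.0400 to 0.00194 and glycolysis from -0.0667 to 0.0112. Glucocorticoid-responsive genes ran from -0.127 to 0.0523, interferon from -0.418 to 0.105, glutamate signalling from -0.0357 to 0.0334, calcium from -0.0472 to 0.00763 and apoptosis from -0.0431 to 0.0116. Endothelium ran from -0.176 to 0.171, meninges from -0.805 to 0.398, thalamus from -0.199 to 0.118 and blood cells from -0.142 to 0.164. The cause was not tested.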

Other observations

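The tests of clock explanations in this part were chosen after the clock genes were seen, except the one on further genes of the Dbp phase, which was fixed before their values were seen; the limit for a slide effect was made stricter after its value was seen.

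Among heat shock genes, Hspa1a had a large difference that missed the threshold, and Hsp90aa1 a smaller one. Hspa1a, the inducible HSP70, was 5.90-fold lower in CCH (log2 -2.56 ± 0.48, SE, n = 4 per group, limma adjusted p = 0.0653; -2.39 on its second probe). Hsp90aa1, the inducible HSP90, was at -0.49 ± 0.08 (SE, limma adjusted p = 0.0562), with -0.70, -0.64 and -0.08 on its other probes. The heat shock list had 8 members higher and 12 lower of 20 (camera adjusted p = 0.630), and 2 were called higher and 3 lower when adjusted over the list alone. In the immediate early list 22 were higher and 11 lower of 33 (camera adjusted p = 0.396), and 2 were called in each direction when adjusted over the list alone. They included Gadd45b, a stress-induced growth arrest gene, at -0.68 ± 0.12 (SE) and the transcription factor gene Atf3 at -0.48 ± 0.12 (SE). That list passed with array weights (adjusted p = 0.0272) and without CCH replicate 1 (0.0301), in a range over all alternatives of 0.0272 to 0.971.

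Neurotrophin and neuropeptide genes included neurotensin, Nts, at a log2 of 0.87 ± 0.19 (SE, limma adjusted p = 0.0878; 0.81 on its second probe). Of 28 members 15 were higher and 13 lower (camera adjusted p = 0.540), and 4 were called higher when adjusted over the list alone. Among markers of nearby regions, thalamus and habenula had 3 higher and 5 lower of 8 (camera adjusted p = 0.970), with the neuropeptide gene Tac3 at 0.44, called when adjusted over the list alone, and Slc17a6 at 0.50 (0.31 with array weights). Neocortex and subiculum had 3 higher and 4 lower of 7 (camera adjusted p = 0.933), with Nts called when adjusted over the list alone. Striatum had 6 higher and 6 lower of 12 (camera adjusted p = 0.567), with Rasd2 at 0.38 and Tac1 at -0.35.

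Cytokine and inflammation genes were lower for 20 of 23 (camera adjusted p = 0.225), with Il1rn, the interleukin 1 receptor antagonist gene, at a log2 of -0.55 ± 0.20 (SE) and the chemokine gene Ccl2 at -0.75 ± 0.34 (SE; -0.45 with normexp). They passed without control replicate 2 (adjusted p = 0.0312) or control replicate 4 (0.0112), in a range over all alternatives of 0.0112 to 0.971. Interferon and antigen presentation genes were lower for 18 of 25 (camera adjusted p = 0.363). They included the antiviral GTPase gene Mx1 at -1.13 ± 0.24 (SE, limma adjusted p = 0.0808; -0.69 with normexp), called when adjusted over the list alone, and the peptide transporter gene Tap2 at 0.56 (0.35 without control replicate 2). They passed without control replicate 4 (adjusted p = 0.00455, in a range of 0.00455 to 0.971), and their mean was 0.11 without control replicate 1. Control replicates 1 to 4 scored 0.47, -0.22, 0.38 and -0.22 for cytokines, 0.99, -0.39, 0.36 and -0.57 for interferon, 1.95, -1.66, 1.34 and -1.19 for meninges and 0.42, -0.15, 0.29 and -0.62 for endothelium, high on replicates 1 and 3 and low on 2 and 4 in all of them. Glucocorticoid-responsive genes were higher for 8 and lower for 12 of 20 (camera adjusted p = 0.907), with Bcl6 at 0.33.

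Clock genes of opposite phase differed in opposite directions, although the list as a whole, 8 higher and 8 lower of 16, was not called (camera adjusted p = 0.966) and no member passed over all probes. Dbp, a clock output gene, was at a log2 of -0.75 ± 0.14 (SE, limma adjusted p = 0.0634), and the repressor genes Nr1d1 and Nr1d2 at -0.60 and -0.35. Bmal1, Npas2 and Cry1 were at 0.36, 0.27 and 0.26, and Nfil3 at 0.32. When adjusted over the list alone, 1 was called higher and 2 lower.

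Of 15 members with a known phase 13 had its sign, and a phase score differed by 0.21 between groups (two-sided exact permutation p = 0.0286, the smallest possible; control -0.19 to -0.04, CCH 0.00 to 0.16). A slide effect on single probes that ignores clock phase stays open despite the 13, and a difference in the time of killing might also give such a pattern. Of 5 further genes of the Dbp phase only 2 were measured, Wee1 at -0.11 and Tsc22d3 at 0.29, and their median of 0.0875 (two-sided exact permutation p = 0.571) leaves it undecided. A shift of the clock by the diet, with the score difference of 0.214, cannot be told apart from it without the time of killing, which the labels do not give and arrays from rats killed at matched hours would supply.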
